A study of Caenorhabditis elegans with 7 samples.

How the data were processed

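The series holds 7 RNA sequencing libraries of early C. elegans embryos, 4 from flp-21(ok889) mutants and 3 from wildtype, grouped by the genotype in the labels. Per the labels' protocols, embryos came from mothers that held few eggs, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

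The authors deposited a table of raw counts of reads per gene for 46748 genes. Per the file headers, it was made with featureCounts 1.6.4, counting exons per gene identifier on trimmed alignments against a WBcel235 annotation. The command gives no option for strand, multiply mapped reads or pairs. The submitters' processing notes also name BWA, DESeq2 and build WBcel235. BWA does not split reads across introns, so reads over exon junctions can go uncounted, and counts of genes with many short exons can be low. Without strand, reads of a gene and of an overlapping or antisense gene cannot be told apart. Reads shared by near-identical copies, such as msp, vitellogenin, histone, clec-209 and pud genes, were not split with certainty. The header lists a further alignment, named as wildtype number 29, with no column in the table and no sample, which was not analysed here. Every count column with a sample was used.

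The authors also deposited a table of their own DESeq2 comparison, with log2 fold changes and standard errors, p-values and adjusted p-values, and the mean signal as counts divided by size factors. It holds 3791 genes, the largest adjusted p being 0.0497 and the smallest absolute log2 fold change 1.5. The version of DESeq2 is not given in the sources used here.

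Gene symbols came from the Ensembl release 115 annotation of WBcel235 and a table of gene names, which gave a symbol for 43894 of the 46748 identifiers. Coordinates are those of the count table. Total counts were 34164612, 35547865, 51882235 and 53620276 in mutant libraries 11, 22, 29 and 30 and 42988763, 34262203 and 36238512 in wildtype libraries 11, 22 and 30, so that 1 count was worth 0.0187 to 0.0293 CPM. A count of 0 was taken to allow up to 3 counts. Intervals and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries were compared by a chi-square test of their counts over genes. The closest pair, mutant libraries 22 and 29, had a chi-square of 25.6 per degree of freedom and all other pairs at least 159, so no 2 libraries agreed within sampling noise. This does not show that mutant libraries 22 and 29 came from separate cultures. Their log2 CPM had a Pearson correlation of 0.992, against 0.94 to 0.973 for the other mutant pairs.

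The main test was the edgeR 4.0.16 quasi-likelihood F-test with robust dispersion in R 4.3.3, TMM normalization, filterByExpr and genotype as the only term. It left 13035 genes, with p-values adjusted by Benjamini-Hochberg and a threshold of 0.05. The processing notes name DESeq2, which was run as an alternative (version 1.42.0). CPM are TMM-scaled unless given as counts. The common biological coefficient of variation was 0.576. After TMM scaling the median log2 fold change of all tested genes was -0.21, against -0.42 with upper quartile, -0.06 with DESeq2 size factors and 0.01 with library size alone, and fold changes are given relative to the TMM scaling. Of the genes called, 76.5% were lower in the mutant with TMM, 84.5% with upper quartile and 67.5% with library size alone.

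There were 27 gene lists, for each of which camera (limma 3.58.1, voom weights) tested whether members moved relative to other genes, with a preset correlation of 0.01. The p-values were adjusted over the 27 lists. In total 18 lists passed, 11 downwards and 7 upwards. With an estimated correlation camera passed 0 of the 27 (2 at an unadjusted p under 0.05), and 12 passed with fry, which tests whether the genes of a list move on balance one way and compares them with no other genes. The mitochondrial genome list was matched by chromosome, since its symbols were not in the annotation. Lists of meiotic germ line and body wall muscle genes were added after seeing the data. The number of changed genes near flp-21 was tested with Fisher's exact test and total counts with an exact permutation test over 35 splits, whose smallest possible p is 0.0286.

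The lists, tests, alternatives and the rule for named genes were set before the data were examined. The rule takes flp-21, npr-1 and npr-5, then the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the libraries of the groups, then up to 3 members of each list with the smallest p-values and a mean of at least 1 CPM. Alternatives covered scaling, tool, count filter, a fold threshold, the number in the label as a block, a stage score as covariate, removal of ribosomal RNA, mitochondrial genome and the 20 most abundant genes, and each library left out in turn. Scores of maternal soma and sperm as covariates, and fits without pairs of libraries, were added after seeing the data. The fit without wildtype libraries 11 and 22 leaves wildtype library 30 alone. Its p-values and counts of passing genes therefore hold no spread between wildtype libraries, and they show only how results depend on the libraries left out.

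The scripts were tested on simulated data for the comparison of mutant and wildtype over 13035 genes. With the observed dispersion the fit recovered 0% of genes changed 2-fold, 18.8% of those changed 4-fold, 56.2% at 8-fold and 75% at 16-fold, and called 4 of 12802 unchanged genes (6 with the lower dispersion named next). With that dispersion divided by 4, recovery was 26.5%, 89.6%, 98% and 93.8%. A shifted proteasome list was found, and 0 other lists were called. Each gene was drawn independently, so the simulation cannot show how often lists of correlated genes are called wrongly. Besides the proteasome list, only 200 genes were changed, as many up as down. In the real data 38.4% of the tested genes were called, most of them lower. The simulated rates of recovery and of wrong calls therefore need not hold for the real comparison. No genome sequence was used here, so GC content was not checked.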

Results

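Gene expression was measured by RNA sequencing in early, pre-gastrulation embryos of the nematode Caenorhabditis elegans from wildtype and from flp-21(ok889) mutant strains. The flp-21 gene encodes a FMRFamide-like neuropeptide, a ligand of the receptors NPR-1 and NPR-5. There were 7 libraries, 4 from the mutant, numbered 11, 22, 29 and 30, and 3 from wildtype, numbered 11, 22 and 30. The series title names maternal provisioning, so the comparison asks which transcripts the embryos of the mutant held at other levels than those of wildtype. Total counts ran from 34164612 to 53620276 per library. They averaged 43803747 ± 10371415 (SD, n = 4) in the mutant and 37829826 ± 4575743 (SD, n = 3) in wildtype, a difference within the spread (two-sided exact permutation test, p = 0.4). At least 10 counts were found for 11462 ± 645 genes per mutant library and 13514 ± 1394 genes per wildtype library. Ribosomal RNA genes took 2.40%, 3.72%, 2.42% and 2.66% of the counts in mutant libraries 11, 22, 29 and 30 and 6.48%, 3.99% and 13.3% in wildtype libraries 11, 22 and 30.

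The mutated gene itself was near the limit of detection. The counts of flp-21 (WBGene00001464, chromosome V from 7793365 to 7794021 in build WBcel235) were 2, 1, 5 and 9 in mutant libraries 11, 22, 29 and 30. They were 24, 2 and 6 in wildtype libraries 11, 22 and 30. At this depth the counts cannot check the genotype labels, and flp-21 stayed under the count filter. The receptor gene npr-1 had 0, 0, 0 and 5 counts in the mutant libraries and 2, 1 and 0 in wildtype, where a count of 0 allows up to 3 counts. The receptor gene npr-5 had 15, 45, 60 and 25 counts in the mutant and 158, 31 and 54 in wildtype. Its log2 fold change was -1.45 (SE 0.69, edgeR quasi-likelihood adjusted p = 0.124), which did not pass the threshold.

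Across the transcriptome, 5004 of 13035 tested genes differed between the genotypes, 1175 higher and 3829 lower in the mutant embryos. The falls were the larger changes: 2720 genes were lower by more than 8-fold and 6 were higher by as much, and the median log2 fold change was -4.07 among genes that fell and 1.46 among those that rose. The first principal component took 73.6% of the variance and separated the genotypes. The libraries of the groups did not overlap for 5809 genes, 44.6% of those tested against 5.71% by chance. The count of higher genes depended on single libraries, being 601, 677 and 589 without mutant library 11, 22 or 29 and 2505 without wildtype library 30. In an alternative chosen after seeing the data, 3292 genes changed without mutant libraries 22 and 29. Another left out wildtype libraries 11 and 22, so that wildtype library 30 stood alone. Wherever that fit is named below, its p-values and counts of passing genes hold no spread between wildtype libraries.

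The gene with the largest rise that met the naming rule was a gene model named lpd-3 (WBGene00021652, chromosome I from 3578692 to 3600677), absent from the annotation used here, at 102 ± 44.9 CPM (SD, n = 4) in the mutant and 10.3 ± 6.93 CPM (n = 3) in wildtype. The insulin/IGF receptor gene daf-2 (WBGene00000898, chromosome III from 2995763 to 3028800) rose 6.84-fold, from 69.8 ± 18.03 to 478 ± 172 CPM (SE of log2 0.44, edgeR adjusted p = 0.00119). The gene rig-4, which encodes an immunoglobulin-domain protein of neurons, rose from 77.6 ± 22.7 to 451 ± 195 CPM (edgeR adjusted p = 0.00335). The anaphase-promoting complex gene apc-17 rose from 8.16 ± 3.72 to 63.0 ± 22.6 CPM, with a log2 fold change of 2.95. C25H3.11, pqn-15, hgap-2 (WBGene00007915), F14H3.3, Y70G10A.1 and fbxa-143 completed the 10 largest rises, with log2 fold changes from 2.54 to 3.23. The call of Y70G10A.1 was the least firm of these (edgeR adjusted p = 0.0464), and fbxa-143 lost its call without wildtype library 22, with the filter of 5 CPM and with the stage score.

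The largest falls were those of 2 near-identical copies of the C-type lectin gene clec-209 on chromosome V, WBGene00018910 and WBGene00021224. The first had 0, 0, 3 and 1 counts in the mutant libraries and 52965, 4648 and 124 in wildtype libraries 11, 22 and 30 (log2 fold change -14.17, SE 1.99, edgeR adjusted p = 8.16e-04). Then came genes named for their abundance in daf-2 mutants, pud-1.1, pud-1.2, pud-3 and 2 copies of pud-2.2, with log2 fold changes from -8.96 to -10.85. These clec-209 and pud genes all lie on chromosome V, that of flp-21, between 2322038 and 2460893. Their falls are therefore linked in position and not spread over the genome. The gene dod-24, named as acting downstream of the daf-16 transcription factor, fell from 64.5 ± 54.2 to 0.0712 ± 0.0488 CPM. The major sperm protein gene msp-38 fell from 327 ± 127 to 0.434 ± 0.300 CPM (edgeR adjusted p = 9.08e-05). ZK84.5 had 1 count over the mutant libraries and 1281 over the wildtype libraries. Relative to total counts, without TMM scaling, this is a 1978-fold difference with a 95% exact interval from 354.3 to 78180 that covers counting error only. The edgeR log2 fold change of ZK84.5, with TMM scaling, was -10.53. Reads of the clec-209, pud and msp copies cannot be assigned with certainty to one copy.

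Changed genes were not concentrated within 5 Mb of the mutated locus. Within 5 Mb of flp-21, 437 of 1174 tested genes (37.2%) had changed, against 4567 of 11861 elsewhere (38.5%), an odds ratio of 0.947 with a 95% interval of 0.835 to 1.07 (two-sided Fisher's exact test, p = 0.396). On the whole chromosome 39.9% had changed, against 38.1% elsewhere (odds ratio 1.08, Fisher's exact test, p = 0.1). The linked clec-209 and pud genes lie outside the window of 5 Mb.

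Transcripts of cytosolic ribosomal proteins were lower in the mutant embryos almost without exception. Of 81 tested genes 77 fell, 0 rose and 4 did not pass, and 78 fell when adjusted over the list alone. Their median log2 fold change was -3.02 (camera adjusted p = 4.33e-23, and adjusted p = 0.509 with an estimated correlation). Together they held 15918 ± 10203 CPM in the mutant and 114074 ± 16114 CPM in wildtype. The large-subunit gene rpl-1 (WBGene00004412, chromosome I from 2875395 to 2876324) fell from 1951 ± 296 to 83.0 ± 32.1 CPM, and rpl-7A from 1442 ± 356 to 69.1 ± 23.7 CPM (edgeR adjusted p = 1.11e-04 and 1.13e-04). The variant gene rpl-25.1 fell from 143 ± 40.02 to 10.5 ± 2.25 CPM. Sperm transcripts and yolk protein transcripts were higher in the same wildtype libraries. Mutant library 30 had the highest level of its group for both the ribosomal list, 31163 CPM, and the sperm list, 514 CPM. Without wildtype libraries 11 and 22, 55 of the 81 genes fell.

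Other parts of the translation machinery had list medians between -0.31 and 0.18, against -3.02 for the ribosomal proteins, and did not pass as lists. Of 44 translation factor genes 6 fell and 2 rose, with a median of -0.31 (camera adjusted p = 0.908). The factors with the smallest p-values were iff-2, an eIF5A gene, which fell from 174 ± 73.8 to 14.5 ± 4.46 CPM, the poly(A)-binding protein gene pab-1, from 2110 ± 730 to 423 ± 103 CPM, and inf-1, an eIF4A gene, from 904 ± 261 to 235.4 ± 53.1 CPM. Adjusted over each list alone, 5 translation factors, 4 tRNA synthetases and 4 mitochondrial ribosomal proteins fell and 0 rose. Among 20 cytosolic tRNA synthetases 4 fell, including wars-1, ears-1 and mars-1 (median -0.25, camera adjusted p = 0.908). Among 69 mitochondrial ribosomal proteins 5 fell, including mrpl-39, mrps-18C and mrpl-35 (median -0.18, camera adjusted p = 0.75). The nuclear-encoded respiratory chain had 2 of 44 members lower, ucr-2.2 and gas-1, and asb-2 at a log2 fold change of -0.87 did not pass (median -0.19, test direction up, camera adjusted p = 0.943). Its median turned to 0.09 with scaling by library size alone. With the filter of 5 CPM the translation factors, the mitochondrial ribosomal proteins and the respiratory chain passed downwards (camera adjusted p = 0.0203, 0.0121 and 0.0228), the mitochondrial ribosomal proteins also without mutant library 30 (0.0357). The mitochondrial ribosomal proteins also passed upwards, without mutant libraries 22 and 29 (camera adjusted p = 0.0271), as did the respiratory chain without wildtype library 30 (0.0441). Of 35 ribosome biogenesis genes 3 fell and 2 rose, nol-6 and grwd-1 among the falls and mtr-4 among the rises (median 0.18, camera adjusted p = 0.0761). The biogenesis list passed upwards without wildtype library 22 (camera adjusted p = 7.38e-04), with the stage score (5.91e-04), with no filter beyond 1 count (0.0146) and with library size alone (0.0484). Of 12 protein genes of the mitochondrial genome 0 changed in edgeR (0 at an unadjusted p under 0.05), COX3 with a log2 fold change of 0.90 (list median 0.24, camera adjusted p = 0.117). That list passed upwards without mutant library 22 (camera adjusted p = 0.0273), wildtype library 11 (0.0398) or 30 (0.0375), without mutant libraries 22 and 29 (0.01025) and with no filter beyond 1 count (0.0331).

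**Figure D1:**
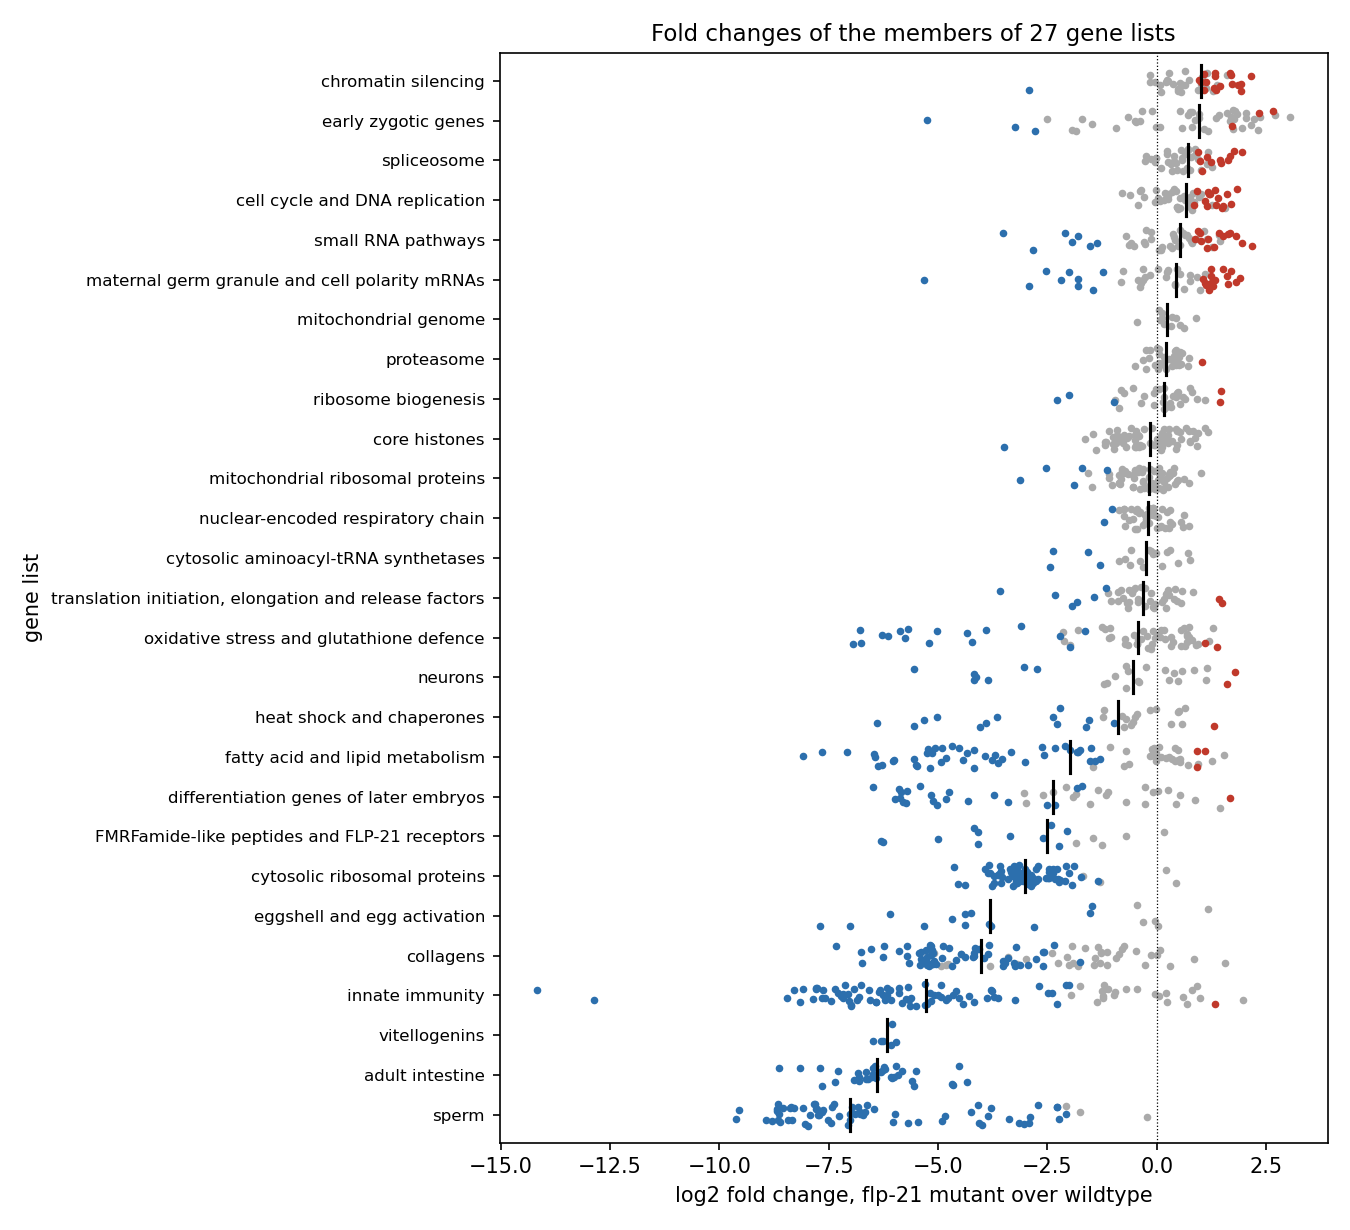
Log2 fold changes (mutant over wildtype, horizontal axis) of the tested members of the 27 fixed gene lists, 1 list per line on the vertical axis. Each point is a gene, red where it rose and blue where it fell at an adjusted p under 0.05, grey otherwise, and black bars are list medians, from -7.02 for sperm genes to 1.02 for chromatin silencing genes.

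Several classes of nuclear and cell division genes were higher in the mutant. Of 45 chromatin silencing genes 17 rose and 1 fell (18 and 1 adjusted over the list alone, median 1.02, camera adjusted p = 2.55e-08, adjusted p = 0.388 with an estimated correlation). The synMuv repressor gene lin-15B rose from 66.6 ± 11.97 to 298 ± 98.2 CPM (edgeR adjusted p = 0.00195). The Polycomb-like gene mes-3 rose from 26.2 ± 5.46 to 99.17 ± 28.999 CPM, and the histone H3 lysine 4 methyltransferase gene set-2, which the list holds although its mark goes with active chromatin, from 68.9 ± 13.05 to 249 ± 85.3 CPM. Of 44 spliceosome genes 11 rose and 0 fell, 6 adjusted over the list alone, among them teg-4, sftb-1 and prp-17 (median 0.71, camera adjusted p = 5.27e-07, adjusted p = 0.388 with an estimated correlation). Of 53 cell cycle and DNA replication genes 15 rose and 0 fell, 13 adjusted over the list alone (median 0.66, camera adjusted p = 1.81e-07, adjusted p = 0.509 with an estimated correlation). The cytokinesis kinesin gene zen-4 rose from 181 ± 22.005 to 512 ± 90.5 CPM, the DNA polymerase alpha gene pola-1 from 207 ± 53.3 to 628 ± 165 CPM and the replicative helicase gene mcm-6 from 347 ± 30.8 to 913 ± 188 CPM. With 1 library left out 11 to 24, 6 to 31 and 7 to 37 members of the 3 lists rose, and 5, 2 and 0 without mutant libraries 22 and 29. As summed levels, spliceosome and cell cycle transcripts of wildtype library 30, at 17461 and 28490 CPM, lay within the range of the mutant libraries. Adult intestine, sperm and collagen transcripts held 8261 to 56935, 10867 to 19826 and 7064 to 45846 CPM in the wildtype libraries, against 6.43 to 1123, 138 to 514 and 29.1 to 1294 CPM in the mutant libraries.

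The proteasome list passed with small changes. Of its 33 members 1 rose, rpt-2, from 382 ± 38.4 to 781 ± 129 CPM, and 0 adjusted over the list alone (median 0.22, camera adjusted p = 0.00573, adjusted p = 0.802 with an estimated correlation). The members rpn-6.1 and rpt-4 had log2 fold changes of 0.74 and 0.59 and did not pass. With library size alone 5 members rose, without wildtype library 30, 24, and with upper quartile scaling 0 in edgeR (1 at an unadjusted p under 0.05). The list call was lost without wildtype library 11 (camera adjusted p = 0.0642), with the filter of 5 CPM (0.252) and without wildtype libraries 11 and 22 (0.539), and the median turned to -0.04 with a stage score as covariate. Of 71 core histone genes 1 fell, his-70, an H3-like variant, and copies such as his-9 (WBGene00001899) and his-41 did not pass (median -0.16, test direction up, camera adjusted p = 0.138). The histone median turned to 0.06 with scaling by library size alone. The histone list passed upwards without mutant library 29 (camera adjusted p = 0.0241), without wildtype library 30 (3.46e-04), without mutant libraries 22 and 29 (0.00172) and with no filter beyond 1 count (0.0395).

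Small RNA pathway genes went both ways. Of 53 members 14 rose and 7 fell, the same numbers adjusted over the list alone (median 0.53, camera adjusted p = 8.88e-04, adjusted p = 0.643 with an estimated correlation). The 3 with the smallest p-values fell against the direction of the list: alg-3 and alg-4, Argonaute genes of spermatogenesis, from 49.9 ± 18.6 to 11.7 ± 1.96 CPM and from 57.1 ± 21.8 to 8.003 ± 2.63 CPM, and the Argonaute gene ppw-2 from 117 ± 88.0 to 10.2 ± 3.82 CPM. With 1 library left out 8 to 18 rose, with upper quartile scaling 9 rose, and without mutant libraries 22 and 29, 2 rose and 4 fell. The list call was lost with the filter of 5 CPM (camera adjusted p = 0.0974). Sperm transcripts were lower along with alg-3 and alg-4, at a summed 242 CPM in the mutant and 15858 CPM in wildtype.

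Maternal messages of the oocyte were split. Among 48 germ granule and cell polarity genes 16 rose and 9 fell, 19 and 9 adjusted over the list alone (median 0.45, camera adjusted p = 0.00744, adjusted p = 0.726 with an estimated correlation). The 3 with the smallest p-values fell: the chitin synthase gene chs-1 from 193 ± 147 to 4.79 ± 1.85 CPM, the Pumilio gene puf-3 from 516 ± 148 to 128 ± 16.8 CPM and the RNA granule gene car-1 from 1481 ± 554 to 326 ± 77.7 CPM. The list call was lost without wildtype library 11 (camera adjusted p = 0.0689), with the filter of 5 CPM (0.252) and without wildtype libraries 11 and 22 (0.350). Without mutant library 29, 5 rose and 8 fell, without wildtype library 30, 29 and 8, and with upper quartile scaling 11 and 10. Eggshell and egg activation genes fell in 13 of 18 cases and rose in 0, against 13 and 1 adjusted over the list alone (median -3.80, camera adjusted p = 1.10e-04, adjusted p = 0.509 with an estimated correlation). The eggshell chondroitin proteoglycan gene cpg-3 (WBGene00011063, chromosome I from 7244937 to 7246295) fell from 786 ± 401 to 11.5 ± 1.83 CPM (edgeR adjusted p = 6.23e-05), cpg-2 from 3043 ± 1239 to 159 ± 37.9 CPM, and the egg surface gene egg-1 from 453 ± 268 to 17.5 ± 2.60 CPM. The eggshell list fell alongside sperm and adult intestine transcripts.

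Genes first transcribed in the early embryo were higher relative to other genes, but few passed singly. Of 50 members 3 rose, 3 fell and 44 did not pass, and 0 rose and 3 fell adjusted over the list alone (median 0.97, camera adjusted p = 7.10e-05, adjusted p = 0.703 with an estimated correlation, fry adjusted p = 0.300). With DESeq2 size factors or library size alone 10 rose and 3 fell, and with upper quartile scaling 2 and 4. Their summed level was 942 ± 175 CPM in the mutant and 478 ± 282 CPM in wildtype, where library 22 held 177 CPM and libraries 11 and 30 held 521 and 736 CPM. The 3 with the smallest p-values were lower in the mutant: the gut transcription factor gene elt-2, from 5.38 ± 4.37 to 0.139 ± 0.0941 CPM, and the posterior Hox genes nob-1 and php-3, with log2 fold changes of -2.79 and -3.23. Differentiation genes of later embryos fell in 21 of 43 cases and rose in 1 (22 and 2 adjusted over the list alone, median -2.36, camera adjusted p = 0.0201, adjusted p = 0.804 with an estimated correlation). The troponin C gene pat-10 fell from 399 ± 264 to 6.82 ± 6.72 CPM, the intestinal intermediate filament gene ifb-2 from 86.7 ± 31.3 to 1.37 ± 1.34 CPM, and the troponin I gene tni-4 from 9.55 ± 4.44 to 0.272 ± 0.114 CPM. With 1 library left out 10 to 24 fell, and 9 with the number in the label as a block. Adult muscle and intestine use these genes too. The list call was lost without mutant library 30 (camera adjusted p = 0.0984), without wildtype library 11 (0.378) and without wildtype libraries 11 and 22 (0.431).

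Yolk and adult intestine transcripts showed very large differences. All 6 vitellogenin genes, which encode yolk proteins made in the mother's intestine, were lower in the mutant, also adjusted over the list alone (median -6.18, camera adjusted p = 0.0183, adjusted p = 0.643 with an estimated correlation). Their summed level was 0.44, 921, 857 and 4.99 CPM in mutant libraries 11, 22, 29 and 30 and 42136, 48599 and 2626 CPM in wildtype libraries 11, 22 and 30. The levels of vit-2 (WBGene00006926, chromosome X from 5101032 to 5106173) were 107 ± 123 CPM in the mutant and 7267 ± 5653 CPM in wildtype (log2 fold change -6.08, SE 2.02, edgeR adjusted p = 0.0396), and vit-1 and vit-6 gave -6.49 and -5.96. The edgeR calls were near the threshold: 0 of the 6 passed when any 1 of mutant libraries 22 and 29 and the 3 wildtype libraries was left out, with the filter of 5 CPM or with the stage score (6 at an unadjusted p under 0.05 in each). Also 0 passed with the number in the label as a block (1 at an unadjusted p under 0.05) and with no filter beyond 1 count or without wildtype libraries 11 and 22 (0 in each). The list call was lost without mutant library 30 (camera adjusted p = 0.0542), with the stage score (0.0630) and without wildtype libraries 11 and 22 (0.186). All 36 tested adult intestine genes fell, vitellogenins included, also adjusted over the list alone (median -6.39, camera adjusted p = 5.25e-12, adjusted p = 0.509 with an estimated correlation). The saposin-like genes spp-1 and spp-8 fell from 45.6 ± 7.93 to 0.800 ± 0.470 CPM and from 22.6 ± 13.2 to 0.0546 ± 0.0463 CPM, and the lipid-binding protein gene lbp-6 from 254 ± 99.9 to 3.96 ± 2.97 CPM. Without wildtype libraries 11 and 22, 12 of the 36 fell, and 27 to 36 with 1 library left out.

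**Figure D2:**
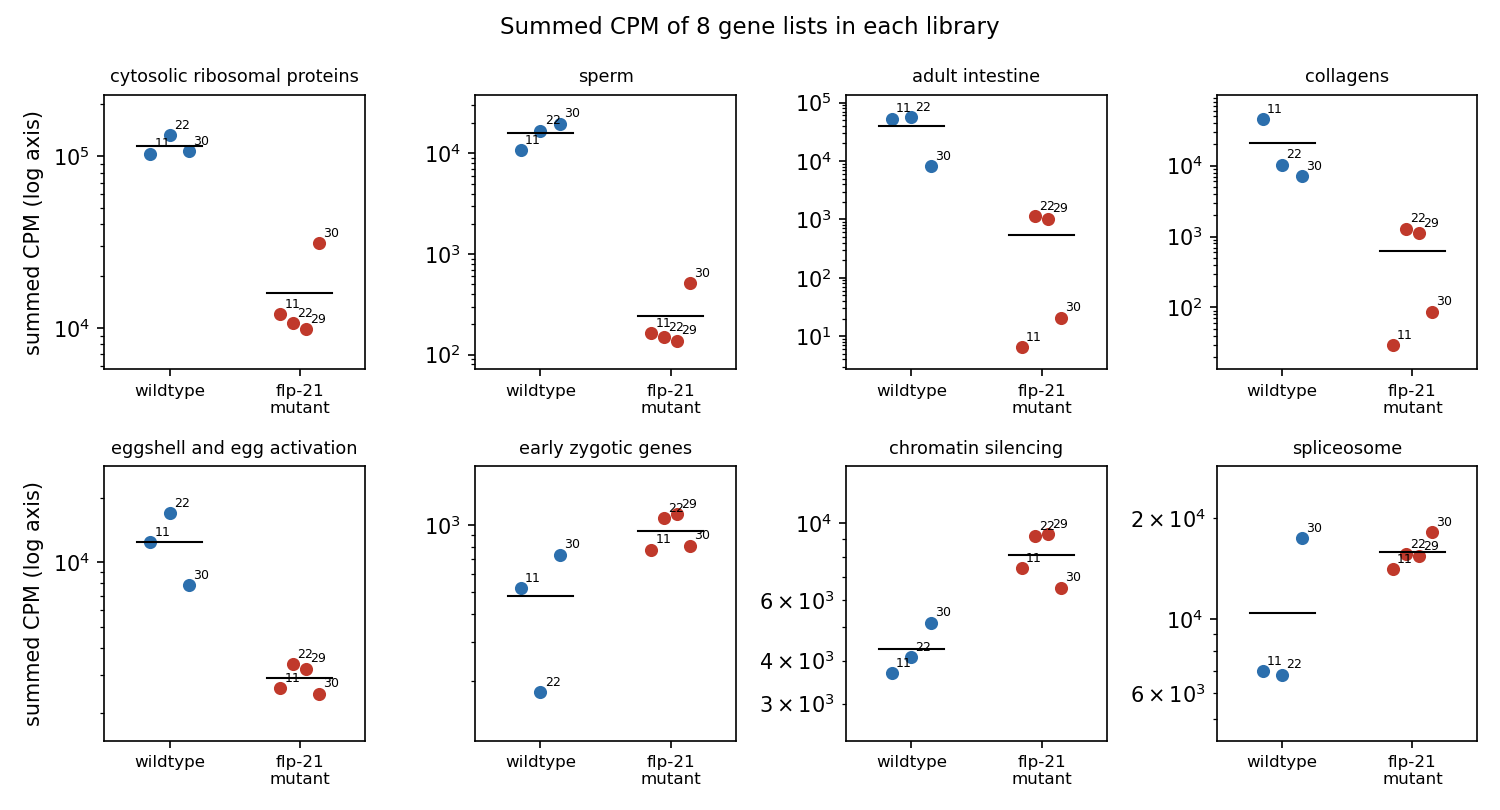
Summed CPM (log axis) of 8 gene lists in each wildtype library (blue) and flp-21 mutant library (red), with the number in the library's label beside each point and a bar at the mean of the group. Ribosomal protein transcripts lie between 9801 and 31163 CPM in the mutant libraries and between 103320 and 132601 CPM in the wildtype libraries, while early zygotic transcripts are lowest in wildtype library 22 at 177 CPM.

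Sperm transcripts fell with few exceptions. Of 71 genes 68 fell and 0 rose, 69 adjusted over the list alone (median -7.02, camera adjusted p = 4.67e-30, adjusted p = 0.509 with an estimated correlation), with 242 ± 182 CPM in the mutant against 15858 ± 4566 CPM in wildtype. The major sperm protein gene msp-78 fell from 389 ± 104.1 to 0.943 ± 0.366 CPM (SE of log2 0.50, edgeR adjusted p = 6.23e-05), and msp-56 and msp-36 had log2 fold changes of -8.29 and -7.66. Without wildtype libraries 11 and 22, 60 of 72 sperm genes fell. Collagen genes of the cuticle fell in 62 of 100 cases and rose in 0, 75 and 1 adjusted over the list alone (median -4.01, camera adjusted p = 7.88e-08, adjusted p = 0.643 with an estimated correlation). The genes col-62, col-12 and col-39 had log2 fold changes of -7.35, -5.66 and -6.27. Without wildtype libraries 11 and 22, 22 of 110 collagens fell, 28 to 59 with 1 library left out, 30 being the count without mutant library 29, and 19 of 100 with the number in the label as a block.

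Defence and lipid genes fell in large numbers. Of 102 innate immunity genes 78 fell and 1 rose, 79 and 2 adjusted over the list alone (median -5.27, or -5.25 with 1 gene without counts in the mutant at its bound, camera adjusted p = 1.93e-12, adjusted p = 0.509 with an estimated correlation), and 46 of 111 fell without wildtype libraries 11 and 22. Their summed level nonetheless differed little, 7095 ± 1395 CPM in the mutant and 8608 ± 2581 CPM in wildtype. The most abundant member, the lectin gene clec-87, at 4212 and 2755 CPM, did not pass (edgeR adjusted p = 0.389). The lectin genes clec-117 and clec-85 fell from 22.8 ± 9.71 to 0.101 ± 0.0597 CPM and from 55.8 ± 1.23 to 0.286 ± 0.217 CPM. Of 75 fatty acid and lipid metabolism genes 45 fell and 3 rose, the same adjusted over the list alone (median -1.99, camera adjusted p = 1.90e-04, adjusted p = 0.509 with an estimated correlation), and 22 fell without wildtype libraries 11 and 22. The genes acs-18, acdh-5 and lbp-5, an acyl-CoA synthetase, an acyl-CoA dehydrogenase and a lipid-binding protein, had log2 fold changes of -7.09, -5.08 and -4.81. Of 30 heat shock and chaperone genes 13 fell and 1 rose, 14 and 1 adjusted over the list alone (median -0.89, camera adjusted p = 0.0276, adjusted p = 0.643 with an estimated correlation). The mitochondrial chaperonin gene hsp-60 fell from 436 ± 284 to 26.4 ± 8.45 CPM, and the small heat shock protein genes hsp-12.2 and hsp-25 had log2 fold changes of -5.55 and -3.90. The chaperone call was lost without mutant library 30 (camera adjusted p = 0.0542), wildtype library 22 (0.0875) or wildtype library 30 (0.0947), without wildtype libraries 11 and 22 (0.0628), with library size alone (0.0526), with no filter beyond 1 count (0.0662) and with the stage score (0.0807). Of 65 oxidative stress genes 17 fell and 2 rose, the same adjusted over the list alone, led by gst-19, gst-26 and gst-13 with log2 fold changes of -6.28, -6.14 and -6.80 (median -0.44, camera adjusted p = 0.397). The innate immunity, lipid and chaperone lists fell alongside adult intestine transcripts, and some innate immunity genes, such as spp-1, also stand on that list.

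Neuropeptide genes were at low levels and lower in the mutant, alongside adult intestine and sperm transcripts. Of 16 tested FMRFamide-like peptide and receptor genes 11 fell and 0 rose, 12 adjusted over the list alone (median -2.50, camera adjusted p = 0.00729, adjusted p = 0.643 with an estimated correlation). Levels were 0.0609 ± 0.0714 CPM for flp-28 and 0.0315 ± 0.0518 CPM for flp-12 in the mutant and 4.68 ± 2.48 and 2.51 ± 1.58 CPM in wildtype, and flp-10 had a log2 fold change of -2.23 (edgeR adjusted p = 0.0191). The call of flp-10 was lost without mutant library 11 or 22, without wildtype library 11 and with the number in the label as a block. In the fit without wildtype libraries 11 and 22, 4 of 17 members fell and the list call was lost (camera adjusted p = 0.119). General neuronal genes did not move as a list: 7 of 26 fell and 2 rose, also adjusted over the list alone (median -0.54, test direction up, camera adjusted p = 0.933). The 3 with the smallest p-values, the touch neuron gene mec-17, the GABA synthesis gene unc-25 and the peptide processing gene egl-21, fell with log2 fold changes of -4.19, -5.56 and -4.13.

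The authors' deposited table lists 3791 genes, 3075 lower and 716 higher in the mutant, each with an absolute log2 fold change of at least 1.5. Of these, 3545 passed the edgeR threshold here, and the sign was the same for all 3545. In the authors' deposited table daf-2 has a log2 fold change of 2.84, rpl-1 of -4.51, cpg-3 of -6.07 and msp-78 of -8.61. The edgeR fit called 4240 genes at that size, of which 757 are not in the authors' deposited table. The DESeq2 fit called 5571 at that size, of which 1885 are not listed, and its log2 fold changes differed from the listed ones by a median of 0.12. The smallest mean signal among the listed genes is 16.3, and their adjusted p-values imply about 11366 tested genes. The DESeq2 fit tested 16682 genes and edgeR 13035, so unlisted genes do not measure disagreement alone.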

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

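In the mutant group, 137 values were examined for a library far from the others, and 18 had 1 library separated from its nearest neighbour by a share of the group's range above Dixon's 95% critical value. Chance gives about 1 in 20 such groups. Wildtype has 3 libraries and was not examined in this way.

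Mutant library 30 stood apart in 10 of them. Its summed CPM was 31163 for cytosolic ribosomal proteins (others 9801 to 12012), 7738 for oxidative stress genes (others 4461 to 4896), 514 for sperm genes (others 138 to 164), 9162 for innate immunity genes (others 6110 to 6630), 26000 for the nuclear-encoded respiratory chain (others 14696 to 15788) and 2399 for core histones (others 1305 to 1376). For single genes it had 35.2 CPM of lpd-3 (WBGene00021652) against 121 to 128, 35.95 CPM of mrps-18C against 19.6 to 21.6, 90.2 CPM of his-41 against 23.7 to 28.6, and 13.5 CPM of syp-4 against 23.3 to 23.9. Wildtype library 30 was likewise the highest of its group for the oxidative stress, sperm, innate immunity, respiratory chain and core histone lists.

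Mutant library 11 was lowest for the neuron list, 315 CPM against 423 to 440, and for col-39, ucr-2.2 and rpt-4, at 0.0731, 20.97 and 552 CPM against 0.858 to 0.903, 30.3 to 31.5 and 681 to 690 CPM. Mutant library 22 was highest for php-3, flp-12 and acs-18, at 1.03, 0.108 and 0.216 CPM against 0.268 to 0.343, 0 to 0.0181 and 0.0903 to 0.0974 CPM. Mutant library 29 held the only count of ZK84.5, 0.0181 CPM. The last 4 values rest on few counts.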

How the results depend on the processing

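The scores of maternal soma and of sperm as covariates and the fits without pairs of libraries were chosen after seeing the data. Over all alternatives, 105 named genes gave 2287 values, of which 1928 kept their direction and side of the threshold, 310 fell short of it, 17 newly passed and 32 turned, that is, changed sign with a passing value in at least 1 of the 2 fits. The 27 lists gave 591 values, 492, 54, 26 and 19 in the same order. With DESeq2 size factors, upper quartile or library size as the scaling, no named gene and no called list turned, and 18 lists passed. The edgeR count of 5004 genes ran from 3804 to 7282 with 1 library left out, of higher genes from 589 to 2505 and of lower genes from 3058 to 4777, and lists from 16 to 20. The count of higher genes, 1175, was 2506 with limma-voom, 1835 with DESeq2, 748 with upper quartile scaling, 660 with the stage score and 589 without mutant library 29. At 5 CPM, where 7695 genes were tested, 2069 changed, 505 higher and 1564 lower. Without wildtype libraries 11 and 22, 2850 changed and 1906 were lower, and without mutant libraries 22 and 29, 3292 changed and 339 were higher, with fewer samples in each. With an estimated correlation 0 lists passed. For these counts, except where fewer genes or samples were used, the cause was not tested.

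The number in the label, as a block, gave 4371 changed genes, 1363 higher and 3008 lower, and 18 lists. Same-numbered libraries deviated from their group means with correlations of -0.2, 0.068 and 0.46 for numbers 11, 22 and 30. So not every library was closest to its own number. This cannot decide whether same-numbered libraries shared a day or culture, since large differences within groups, such as in yolk transcripts, enter the deviations too. The value for number 30 was the highest of any mutant and wildtype pair. Mutant and wildtype libraries 30 held 26000 and 29568 CPM of the respiratory chain (others 14696 to 16051). They held 2399 and 2655 CPM of core histones (others 696 to 1376). Whether they shared a batch was not tested. With the block, 8 named genes fell short of the threshold and 1 newly passed. Mutant library 29 has no partner among the samples, since the wildtype alignment of that number has no counts. So the fit to set beside the block is the 1 without mutant library 29 and without a block. Between these 2 fits the members that fell went from 30 to 19 for collagens (62 with all libraries and no block), from 16 to 9 for differentiation genes (21), from 28 to 22 for adult intestine (36) and from 19 to 11 for body wall muscle (21). In both, edgeR called 0 vitellogenins (6 and 1 at an unadjusted p under 0.05).

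With the soma score edgeR called 224 genes, 11 higher and 213 lower (2785 at an unadjusted p under 0.05), and log2 fold changes turned for clec-209 (WBGene00018910) to 3.55, pud-3 to 3.58, vit-1 to 6.76, vit-6 to 5.80 and vit-2 to 5.83. The score holds the vitellogenins themselves. The calls of adult intestine, collagens, body wall muscle, lipid, chaperone and FMRFamide-like peptide genes were lost. List medians turned for vitellogenins to 6.56, differentiation genes to 0.54, neurons to 0.56, proteasome to -0.61 and the added list of body wall muscle to 0.07. With the sperm score edgeR called 0 genes, 0 higher and 0 lower (1935 at an unadjusted p under 0.05). This score shared 0.973 of its variance with genotype. Turned log2 fold changes were -5.47 for lpd-3 (WBGene00021652), -5.74 for C25H3.11, -4.43 for pqn-15, -2.80 for apc-17, -5.01 for hgap-2 (WBGene00007915), -2.36 for daf-2, -0.18 for F14H3.3, -1.61 for fbxa-143 and -4.58 for rig-4. In the lists they were 0.34 for mrpl-39, 1.55 for mrps-18C, 3.13 for mrpl-35, -3.68 for mtr-4, -1.39 for lin-15B, -1.62 for mes-3, -2.14 for set-2, 0.50 for alg-4, 0.89 for gas-1 and 6.18 for his-70. The others were -0.47 for teg-4, -1.20 for sftb-1, -2.04 for prp-17, -0.20 for zen-4, -0.26 for pola-1, -0.83 for mcm-6 and -1.70 for him-17. List medians turned to 2.11 for ribosomal proteins, 2.26 for translation factors, 4.53 for mitochondrial ribosomal proteins, 1.91 for oxidative stress, -0.70 for chromatin silencing, -1.02 for small RNA pathways, -0.25 for early zygotic genes, 3.92 for the respiratory chain and 4.78 for core histones.

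The proteasome median was -0.0369 with the stage score and -0.30 without wildtype libraries 11 and 22, where syp-4 turned to 0.46. Without mutant libraries 22 and 29 the medians of mitochondrial ribosomal proteins and core histones were 0.16 and 0.27. Without wildtype library 30 those of the respiratory chain and core histones were 0.35 and 0.88, and with any 1 library left out core histones ran from -0.58 to 0.88. For these turns the cause was not tested. Medians of lists that passed in neither fit changed sign too. Neurons went to 0.83 without wildtype libraries 11 and 22, 0.30 at 5 CPM and 0.13 without wildtype library 11. The mitochondrial genome went to -1.35 with the soma score, -0.36 with the stage score, -0.17 without mutant library 30, -0.06 without wildtype library 22 and -0.02 at 5 CPM. Ribosome biogenesis went to -0.49 with the sperm score and -0.07 at 5 CPM, and tRNA synthetases to 0.34 with the sperm score and 0.0022 without wildtype library 22. Mitochondrial ribosomal proteins went to 0.11 without wildtype library 22 and 0.0078 with the stage score, and translation factors to 0.23 without wildtype library 30. Core histones went to 0.15 with the block and 0.06 with library size alone, and the respiratory chain to 0.09 with library size alone. The fold of genes with few counts in the mutant, such as clec-209 and ZK84.5, is limited by depth.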

Other observations

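The tests with the soma and sperm scores, the tests on wildtype library 22 and the lists of body wall muscle and meiotic germ line genes were chosen after the result was seen. Body wall muscle genes fell in 21 of 26 cases and rose in 0, 22 and 0 adjusted over the list alone (median -4.97, camera adjusted p = 6.91e-07, adjusted p = 0.617 with an estimated correlation). The calsequestrin gene csq-1 fell from 56.6 ± 39.6 to 1.39 ± 1.13 CPM, and the actin-binding protein gene unc-87 from 127 ± 111 to 4.24 ± 3.13 CPM. Without wildtype libraries 11 and 22, 2 of the 26 fell, and 13 to 23 with 1 library left out. Meiotic germ line genes moved little: 5 of 36 rose and 3 fell, 0 and 0 in edgeR adjusted over the list alone (14 at an unadjusted p under 0.05, median 0.20, camera adjusted p = 0.0084, adjusted p = 0.617 with an estimated correlation), and the list call was lost with the filter of 5 CPM (camera adjusted p = 0.173). The germline stem cell gene lst-1 and the meiotic gene him-17 had log2 fold changes of 1.25 and 1.32, and the synaptonemal complex gene syp-4 of -1.99.

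Transcripts of adult intestine, sperm, cuticle collagens and body wall muscle, summed per list, were lower in each mutant library than in each wildtype library. The choice among the scalings used here was argued against as a source. It moved the median log2 fold change of all tested genes only between -0.42 and 0.01, against list medians of -4.01 to -7.02. The lowest ratio of a list's median under another scaling to that under TMM was 0.96. It was taken over the sperm, intestine and collagen lists, and so small a shift fixed it in advance, so it adds no support. RNA of maternal tissue in the wildtype libraries is a candidate explanation that stays open: the 7 of 16 pharynx genes that could be tested, none of them on another list, had a median log2 fold change of -1.76, but 2 fell (ifa-4, -5.48, and myo-5, -3.38) and nep-1 rose by 1.80. The first bound for this test, a median under -1, would have counted it for maternal tissue, and the demand that at least as many members fall as do not was added after the value was seen. An effect of the genotype on what these samples hold was not tested apart from it.

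Ribosomal protein mRNAs were lower by a median log2 fold change of -3.02. A loss of short transcripts was argued against. Genes matched on length and level, 5 for each ribosomal gene, had a median of 0.124 with repeats counted. Over the 136 different ones the quartiles were -0.46 and 0.67, against -3.31 and -2.47 for the list. Fitting a stage score, the mean log2 CPM of early zygotic genes, gave -2.93. The score was -1.13 in wildtype library 22 and 1.82 to 2.22 in all others, so it mostly took up that library. The fit therefore cannot decide whether the embryos were of another stage. Wildtype libraries 11 and 30 had scores near those of the mutant, so the level of early zygotic genes did not account for the difference. RNA of maternal soma was not decided by the soma score. With this score the median was -4.04 (camera adjusted p = 9.68e-39), but 1 of 81 genes then passed. The score shared 0.797 of its variance with genotype, and the same fit turned the vitellogenins, which the score holds, to 6.56. Within wildtype, ribosomal levels did not follow those of adult intestine, though this rests on library 30. Wildtype libraries 11, 22 and 30 held 53057, 56935 and 8261 CPM of adult intestine transcripts and 103320, 132601 and 106301 CPM of ribosomal ones. RNA of sperm or gonad cannot be told apart from the genotype, since the sperm score gave 2.11 with a variance inflation of 37.4, and a change in maternal supply may also stand behind the difference, which was not tested.

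Wildtype library 22 held 177 CPM of early zygotic transcripts, and was the lowest of the 7 libraries for 40 of 50 genes (80%, against 14.3% by chance). Dilution by RNA of maternal soma alone was argued against: relative to wildtype libraries 11 and 30 the germ granule and polarity list stood at 1.07 and the zygotic list at 0.282, a ratio of 3.8, with quartiles over genes of 0.716 to 1.53 and 0.0621 to 0.285. The first bound for this ratio was 4, under which the test decided nothing, and it was lowered to 2, with the demand that the quartiles part, after the value was seen. Dilution by RNA of gonad cannot be told apart, since gonad RNA holds the same oocyte mRNAs, and the eggshell and meiotic germ line lists stood at 1.68 and 1.27 in this library. Embryos collected before the onset of zygotic transcription stay an open explanation, since the 80% restates the low level that prompted the test and cannot count for it, and no biological explanation was tested.

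X-linked genes had a median log2 fold change of -0.33 (1504 genes) and autosomal genes of -0.16 (10784 genes), a difference of -0.168 that is smaller than the 0.5 set as the bound for an X-linked effect.

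Of the 35 splits of the 7 libraries into 4 and 3, 1, the real one, gave as many as 5004 edgeR genes. The highest other, 1647, set mutant libraries 11, 22 and 29 against the rest. Chance division of the libraries is thus an unlikely source of the number of genes, though the smallest possible p with 35 splits is 0.0286. A batch or admixed RNA that follows the genotype would give the same count, so the splits cannot decide the cause. For the number of lists chance stays open, as 13 of the 35 splits gave at least the 18 of the real one, the highest other giving 21.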
